A study of Drosophila melanogaster with 2 samples.

How the data were processed

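S2R+ cells were profiled by in-situ Hi-C with the restriction enzyme DpnII, per the labels' protocols. Reads were processed with Bowtie and the dm3 assembly, per the submitters' processing notes, which give no version; further steps are not given in the sources used here. The deposited tables hold whole-number counts of contacts for pairs of bins at 6 bin sizes, and a whole-number count per bin taken here as restriction fragments or fragment ends, since per the file headers it is only a count. Each deposited table also holds the authors' expected value for every bin pair, a score that had no distance term: dividing out 1 factor per bin reduced the SD of its natural logarithm from 0.579 to 0.0014 at 160 kb, and from 0.682 to 0.0056 for pairs within major arms at 10 kb. Each pair was listed in both orders and was counted once. The maps at 40, 80 and 160 kb held 111363301 contacts within arms and 13927040 between arms. Those at 5, 10 and 20 kb held pairs of the same arm up to 5, 10 and 20 Mb apart, with 102653918, 108428143 and 111161797 contacts. Both samples are represented by 1 map, so no sample was compared with another and no replicate could be left out.

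The arm ends in the tables (27900000 for 3R) differ from the last gene ends of the annotation at hand, which is of release 6 (32068441 for 3R). No gene position of that annotation was therefore used, and the gene lists that had been planned were not tested. The 4 region pairs are windows of 1 Mb placed by textbook positions of genes on dm3, which were not checked against an annotation.

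Maps were balanced by iterative correction per arm, without the diagonal and the next one, after leaving out bins under 0.25 of the arm's median coverage (472 of 11899 bins of 10 kb). The insulation score was the log2 mean of distance-normalized contact across a bin, over pairs 20 to 100 kb apart, relative to the arm mean. Boundaries were its minima with a prominence of at least 0.2. Contact within and across domains was compared at each distance, and 1000 circular shifts of the boundaries along each arm gave the reference. Compartments used the first eigenvector of the correlation of distance-normalized contacts at 40 kb, and the strength was the mean contact within each outer 20% of bins over that between them. Contacts between arms were balanced at 160 kb without those within arms. Distal contacts were bin pairs at 40 kb over 1 Mb apart with observed over expected of at least 4 and a Benjamini-Hochberg adjusted Poisson p under 0.01 over 788083 pairs, merged within 2 bins. Poisson and binomial errors cover counting error only, and PCR copies are not independent molecules.

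The text names, by a rule fixed before the data were examined, the most prominent boundary and the longest domain of each major arm, the 10 highest distal contacts, 4 region pairs, and the highest and lowest arm pairs. The main settings, tests and most alternatives were fixed then too. The eigenvector is reported as fixed. A centred version and one without the arm-scale trend were added after its results were seen, as were a random split of the contacts into 2 equal parts, the median contact between arms, a permutation of arm labels, compartment strength between arms and thinned autosomes. The random split gave 606 and 603 boundaries, of which 94.7% of the first lay within 10 kb of the second; this measures counting error, not variation between cultures.

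The procedures were tested on simulated maps, which had the contact decay of 3R except in the test of the Rabl-like arrangement. Of 117 planted boundaries 100% were found within 1 bin, and a map of 2000 bins without domains gave 1 boundary. All 20 planted distal spots of 8 times the background were found, and none was called without them. No weaker spots were planted, so this does not test calls near the threshold of 4. The simulated map without spots gives no rate of false calls for the 162 distal contacts of the data. Planted compartments gave strengths of 1.51 with the fixed eigenvector, 1.51 with the centred one and 1.50 with the trend removed. Without compartments the strength was 0.957 with the fixed version and 0.972 with the trend removed, but 1.13 with the centred one. That map had no domains either, so it gives no strength for a map with domains but without compartments. The planted Rabl-like arrangement gave a mean rho of -0.651. There, contact between arms of equal length depended only on the difference of distance from the centromeric end, which is simpler than the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.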

Results

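In-situ Hi-C, which ligates DNA ends that lie close together in fixed nuclei and counts the ligated pairs, was applied to S2R+ cells, a cultured line of Drosophila melanogaster derived from late embryos. The 2 samples form 1 group of wild-type cells that had been given double-stranded RNA against EGFP, a sequence foreign to the fly. The deposited maps hold 125290341 contacts between bins of the dm3 assembly and do not separate the 2 samples. No error between replicates can therefore be given. Errors below are SDs over the 5 major chromosome arms (2L, 2R, 3L, 3R and X), which are not replicates, or counting intervals. Of all contacts, 88.9% joined loci of the same arm (the 95% Wilson interval, which covers counting error only, is narrower than the rounding) and 11.1% joined different arms.

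The X chromosome carried about 0.545 of the contacts of an autosomal arm at equal numbers of restriction fragments. Its median was 219 contacts per fragment entry in bins of 10 kb, against 401 ± 30.2 (SD, n = 4 arms) on 2L, 2R, 3L and 3R. X was the lowest of the 5 arms. An exact one-sided permutation of 1 arm against 4 cannot give a p below 0.2, and gave p = 0.2.

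Contact fell with distance in a broadly similar way on every major arm. The slope was measured over 3 ranges fixed beforehand, and no breaks between them were tested. The slope of log10 contact on log10 distance was -0.701 ± 0.0364 (SD, n = 5 arms) from 10 to 100 kb. It steepened to -1.33 ± 0.0309 from 100 kb to 1 Mb and was -0.934 ± 0.0404 from 1 to 10 Mb. At the shortest distances X was steeper (-0.762) than any autosomal arm (-0.709 to -0.676). From 100 kb to 1 Mb X was shallower than any (-1.28 against -1.37 to -1.33). From 1 to 10 Mb it was again steeper (-0.997 against -0.951 to -0.896).

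**Figure D1:**
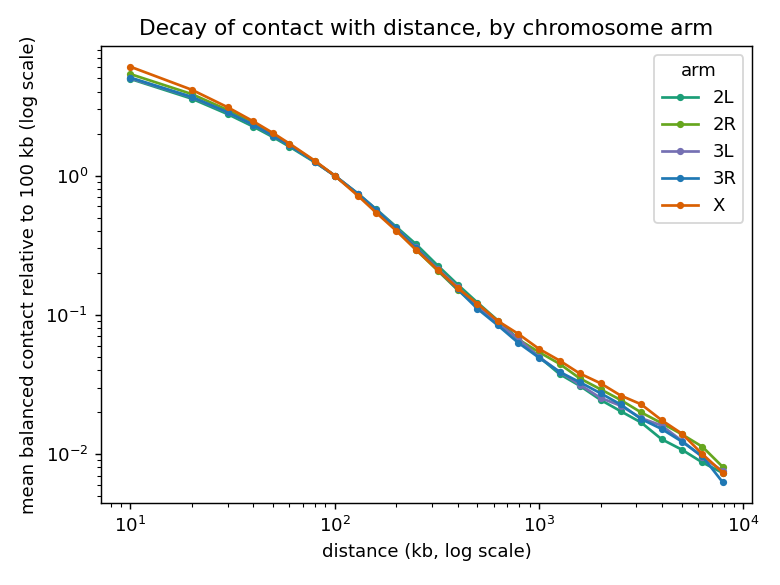
Mean balanced contact (y axis, relative to 100 kb, log scale) against distance (x axis, kb, log scale), 1 line for each of the 5 major arms. The lines nearly overlap, and the slope from 100 kb to 1 Mb is -1.33 on average.

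The series title names topologically associating domains (TADs), stretches of chromosome whose loci contact each other more than loci outside, as structural units. The arms divided into 594 domains with a median size of 170 kb (quartiles 130 and 230 kb), set apart by 600 boundaries. There were 5.26 ± 0.283 boundaries per Mb (SD, n = 5 arms), from 103 boundaries on 2R to 140 on 3R. The most prominent boundary of X lay at 7600001 to 7610000 (insulation -2.02, log2) and that of 3R at 7040001 to 7050000 (-1.78). Those of 2L (16260001 to 16270000), 2R (12470001 to 12480000) and 3L (13020001 to 13030000) had insulation of -1.53, -1.52 and -1.23. The boundary named on 2L had no called boundary within 20 kb under raw contacts or the authors' expected values. The longest domains measured 540 kb on 2L (21230001 to 21770000), 550 kb on 2R (1000001 to 1550000), 420 kb on 3L (17040001 to 17460000), 470 kb on 3R (14990001 to 15460000) and 420 kb on X (11930001 to 12350000). Only 68.5% and 74.5% of the bins of the first and second of these passed the coverage filter. The longest domains depended on the settings: the domain at the same midpoint shrank to as little as 280 kb on 2R, 160 kb on 3L, 170 kb on 3R and 240 kb on X under an alternative, and ranged from 440 to 620 kb on 2L. The number of boundaries depended on the scale of the window, with 984 at 50 kb and 354 at 200 kb. Of all 600 boundaries, 51.7% had a called boundary within 20 kb with the 200 kb window. The share was 81.2% at a prominence of 0.4, 83.8% with raw contacts and at least 84.8% in each other alternative. A change of prominence only adds or drops minima of the same score, so the shares under those settings were fixed in advance. No share for shifted positions was computed for comparison.

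**Figure D2:**
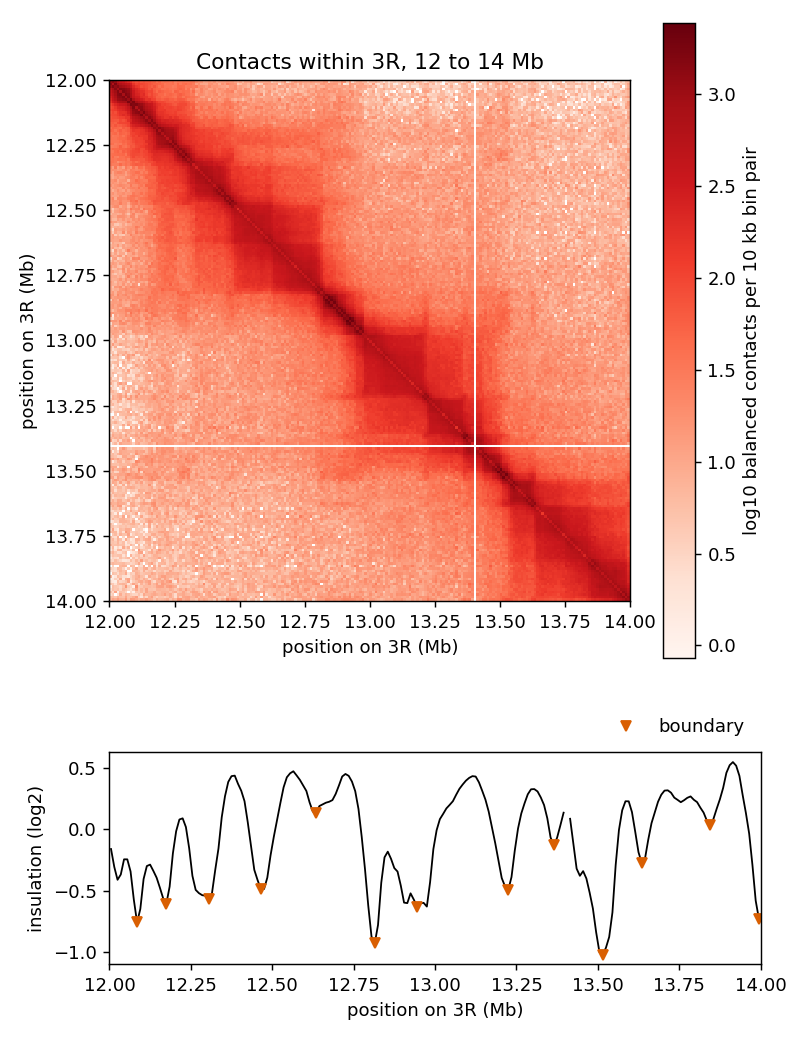
Balanced contacts between bins of 10 kb on 3R from 12 to 14 Mb (upper panel, log10 colour scale, both axes in Mb) and the insulation score (lower panel, log2) with called boundaries as triangles. Squares of high contact along the diagonal end near the triangles, for example at the boundary of lowest insulation in the window (-1.02); the white line is a bin left out for low coverage.

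Loci within 1 domain contacted each other 1.68 times as often as loci of different domains at the same distance, between 20 and 100 kb (SD 0.116, n = 5 arms). The highest of 1000 circular shifts of the boundaries gave 1.05 (p = 0.000999, one-sided permutation, the smallest that 1000 shifts can give). The boundaries came from these same contacts, so that ratio describes the map only. At 110 to 200 kb, distances that did not enter the insulation score, the ratio was 1.95 (SD 0.104, n = 5 arms). The highest of 1000 shifts was 1.10 there (p = 0.000999, one-sided permutation). These contacts come from the same libraries, and the shifts measure chance along this map, not variation between cultures.

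**Figure D3:**
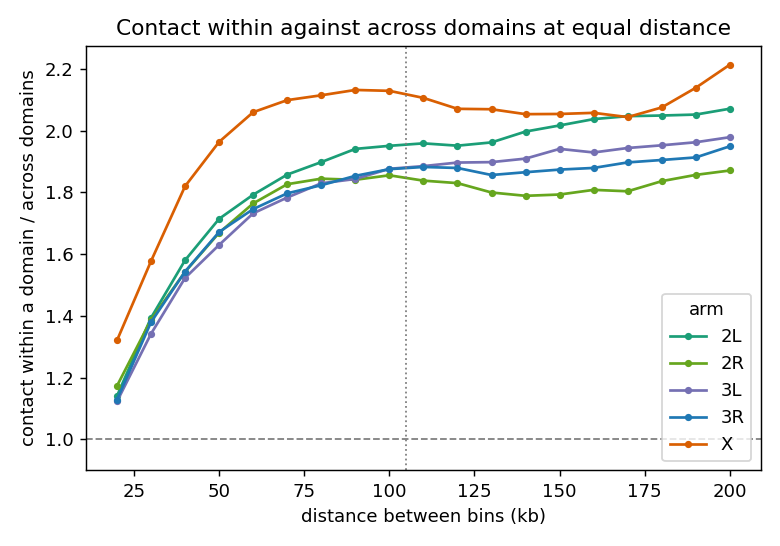
Ratio of contact within a domain to contact across domains (y axis) against distance between bins (x axis, kb), 1 line per arm; distances right of the dotted line did not enter the boundary calls. Every arm lies above 1 at all distances, and X has the highest mean ratio in both ranges (1.89 and 2.09).

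Boundary bins were richer in restriction fragments than shifted positions, with 66.5 against 50.9 fragment entries per 10 kb (1.31 times, two-sided permutation p = 0.000999). Their raw contacts were 1.08 times those of shifted positions (two-sided permutation p = 0.000999). Balancing divides out differences in total contact per bin.

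Compartments are sets of loci, often scattered along a chromosome, that contact their own kind. With the first eigenvector of the correlation matrix, the measure fixed before the data were examined, contact within the outer classes was 1.36 times that between them (SD 0.305, n = 5 arms; highest of 1000 shifts 1.17, one-sided permutation p = 0.000999). The eigenvector came from these same contacts, so that ratio and its p describe the map only. In contacts between arms of different chromosomes, a check added after the data were seen, the same classes had a strength of 1.11 (highest of 1000 shifts 1.07, one-sided permutation p = 0.000999). Within arms the values differed widely: 1.68 on X, 1.61 on 2L and 1.42 on 3L, but 1.09 on 3R and 0.996 on 2R. In bins of 160 kb the mean was 1.11 and no longer passed the test (one-sided permutation p = 0.159). The eigenvector had 1 sign in 89.1% (2L) to 98.4% (2R) of the bins of an arm, so it split the arms poorly into classes.

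Changes of sign of that eigenvector did not fall near domain boundaries more often than chance. Of 95 changes, 38.9% lay within 40 kb of a boundary, against a mean of 40.7% over shifts (one-sided permutation p = 0.673). At 20 kb the share was 27.5%, and no shift was lower (mean 40.8%). Domains still accounted for 81.6% of its variance, against at most 78.9% in 1000 shifts (one-sided permutation p = 0.000999).

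After these results had been seen, 2 further versions of the eigenvector were computed, making 3 in all. Centring the correlation matrix gave a strength of 1.82, and removing the trend over 1 Mb gave 1.66 ± 0.141 (SD, n = 5 arms), with 1.55 on 2R and 1.57 on 3R. Sign changes then lay near boundaries in 55.4% and 54.5% of cases, above all shifts (p = 0.000999 for each, one-sided permutation, not adjusted for the 3 versions). These versions differ from the fixed one in the call on sign changes, so the call rests on a choice made after the fact. Eigenvector and boundaries also come from the same contacts. With the trend removed the sign changed 713 times along arms with 600 boundaries, and 1 class held 7.89 boundaries per Mb and the other 1.74. That difference describes the map only: the sign of each arm was set by boundary density, and the classes were not shown to differ from a split of bins at boundaries from the interiors of domains.

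Arms of the same chromosome contacted each other more than arms of different chromosomes, a comparison that bears on chromosome territories. The ratio to the value given by arm totals was 1.38 for 3L with 3R and 1.32 for 2L with 2R, the highest of the 10 pairs. The 8 pairs of different chromosomes averaged 0.915 ± 0.159 (SD, n = 8 pairs), from 0.737 for 2R with 3L to 1.23 for 2R with X. Same-chromosome pairs were 1.48 times as high (exact one-sided permutation of pair labels p = 0.0222, the smallest possible). The 10 pairs share 5 arms and are not independent: an exact permutation of arm labels, added after the data were seen, has 15 arrangements and gave its smallest p, 0.0667, so it cannot pass 0.05.

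In a Rabl-like arrangement centromeres gather at 1 side of the nucleus and telomeres at the other, so loci at like distances from the centromere meet more often. Contact between arms of different chromosomes fell with the difference of distance from the centromeric end (mean Spearman rho -0.184 over 8 arm pairs, across bin pairs that are not independent; one-sided permutation p = 0.004 over 1000 shifts). The lowest shift, -0.195, was beyond the observed value. The strongest were 2R with 3L (-0.448) and 2L with 3L (-0.383), while 2R with 3R (0.0624) and 3R with X (0.0432) were above 0. In bins of 80 kb the rho was smaller, at -0.111 (one-sided permutation p = 0.0140). The call was lost without 2 Mb at each end of the arms (rho -0.0810, permutation p = 0.192) and with raw contacts (-0.00926, p = 0.430).

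**Figure D4:**
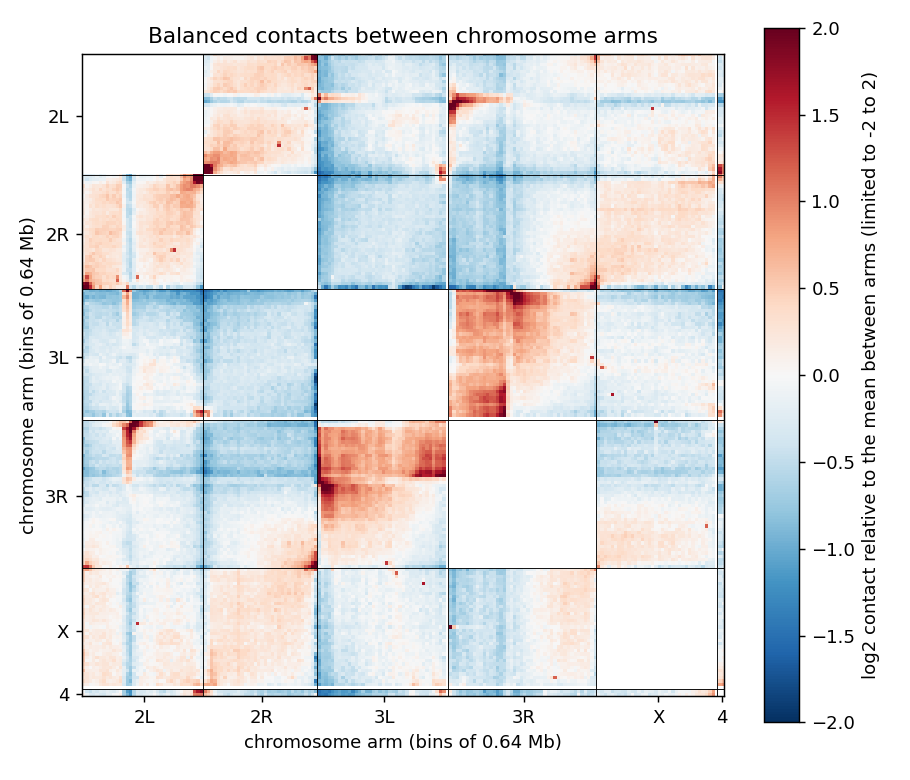
Balanced contacts between arms in bins of 0.64 Mb (log2 relative to the mean between arms, limited to -2 and 2), with arms in order on both axes and contacts within an arm left blank. The blocks of 3L with 3R and 2L with 2R are mostly above the mean, and compact blocks of high contact join 2L with 3R and the ends of arms.

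Within arms, 162 distal contacts over 1 Mb apart stood at 4 or more times the value for their distance. Of these, 85 were a single bin pair and 28 held 10 or more. They were uneven over arms, with 61 on 3R, 45 on 2L, 36 on X, 11 on 2R and 9 on 3L. Many shared an anchor. Several on 3R had 1 anchor at 1 to 40000, its centromeric end, and several on 2L had 1 at 21640001 to 21680000. The 162 are therefore not separate loci, and the counts per arm include repeated calls of the same bins. Some rested on few contacts, such as 7 where 1.17 were expected on X. The highest joined 2L 7480001 to 7520000 with 21200001 to 21240000 at 72.6 times (1197 contacts, 16.5 expected). The next joined 3R 2120001 to 2160000 with 14040001 to 14080000 at 45.9 times. On 3L, 12600001 to 12640000 met 16280001 to 16320000 at 26.8 times, and on 3R, 20320001 to 20360000 met 26880001 to 26920000 at 25.3 times. The remaining 6 of the highest 10 lay between 16.3 and 19.0 times. The number depended strongly on bin size, with 1242 at 20 kb and 42 at 80 kb, and was 628 with raw contacts. The named 10 stayed at 4 or more, within 1 bin of the named place, in all 40 values computed with other bin sizes, raw contacts or no coverage filter.

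**Figure D5:**
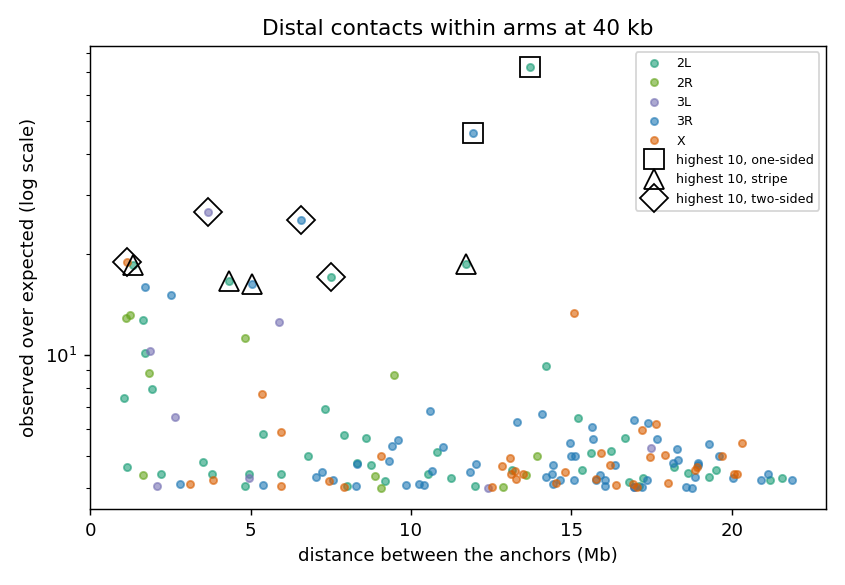
Observed over expected contact (y axis, log scale) against distance between anchors (x axis, Mb) for the 162 distal contacts, coloured by arm. Open symbols mark the shape of the highest 10; the 2 one-sided contacts are the highest, at 72.6 and 45.9.

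By the highest bin pair, the measure fixed beforehand, none of the 4 chosen region pairs stood out as high, and 1 was low. The window on 3R holding the Antennapedia complex (2 to 3 Mb), homeotic genes of the head and anterior thorax, and that holding the bithorax complex (12 to 13 Mb), homeotic genes of the posterior body, reached 3.07 times at their highest bin pair. That was the 77.6th percentile of 67 blocks at the same distance. The window of the tinman and ladybird genes (17 to 18 Mb) was at percentile 59.5 with the first and 68.5 with the second. The window of wingless and other Wnt genes on 2L (7 to 8 Mb) with that of escargot and snail (15 to 16 Mb) was at percentile 1.30, the lowest of 77 blocks, and at or below percentile 8.43 in every alternative. No test was made of this low value. By the mean contact of the block, the 4 pairs stood at percentiles 83.6, 64.3, 83.7 and 5.19, in the order given. Over the alternatives, the highest bin pairs of the region pairs on 3R ranged from percentile 25.0 to 87.5. The windows at 2 to 3 Mb on 3R and 7 to 8 Mb on 2L each hold an anchor of 1 of the 2 highest distal contacts. The highest bin pairs of the first and the last region pair lay in the bin next to that anchor, so these percentiles are not independent of the distal contacts. The windows were taken from textbook positions and not checked against genes.

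The ratio of contact within to across domains was higher on X than on any autosomal arm, but X is 1 arm and this was not tested. At 20 to 100 kb it was 1.89 on X against 1.64 ± 0.0266 (SD, n = 4 arms, highest 1.67). At 110 to 200 kb it was 2.09 against 1.91 ± 0.0799 (highest 2.01). There the margin over the highest autosomal arm was smaller than the SD over autosomal arms. Domains of X had a mean size of 166 kb (SD 67.4, 121 domains) against 187 kb (SD 79.9, 473 domains) on the autosomes (two-sided permutation over domains, which are not replicates, p = 0.00971). The difference in size was not stable: with a window of 50 kb it was 0.475 kb (permutation p = 0.921), and it missed the threshold with a window of 200 kb (p = 0.213), a prominence of 0.1 (p = 0.0750) and raw contacts (p = 0.315). It was larger at a prominence of 0.4, where domains of X were 40.7 kb smaller (permutation p = 0.0002). With thinned autosomes they were 20.6 kb smaller (permutation p = 0.0109).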

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

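Chromosome 4 and contacts between single loci of different arms entered no comparison of the report, and the sizes of their signals are given here. The division of the distal contacts by shape, the separate values of the two-sided and stripe contacts and the test of X beyond 100 kb were chosen after the result was seen. The compartment classes weighed here are those of the eigenvector without the arm-scale trend, itself chosen after the fact.

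Chromosome 4, a small and largely heterochromatic chromosome, contacted the 1.92 Mb nearest the centromere of the major arms 2.09 times as often as the rest of those arms (SD 0.679, n = 5 arms). All 5 arms were above 1, from 1.24 on 3R to 3.02 on 2L, and the highest of 1000 shifts was 1.61 (one-sided permutation p = 0.000999).

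Between arms, 83 merged blocks of 80 kb bin pairs reached 4 times the mean of their arm pair. The largest held 429 bin pairs, and its peak joined 2L 9520001 to 9600000 with 3R 1120001 to 1200000 through 6385 contacts where 67.4 were expected. The median bin pair 1.04 Mb apart on an autosomal arm held 520 contacts.

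The highest 10 distal contacts within arms were divided by shape. In 2, called one-sided, the highest quadrant around the peak held at least 4 times the contact of the lowest. In 4, called stripes, contact along 1 bin was at least 3.5 times that beside it. The remaining 4 reached neither value. They are called two-sided here, but no two-sided pattern was tested. A junction of rearranged chromosomes is a candidate explanation, and would lower contact across the anchors in the reference order. The median percentile of the anchors among all positions was 9.63 at the one-sided contacts (highest anchor 65.4). It was 7.84 at the two-sided ones (highest 76.5), so contact was low across most but not all of these anchors. A domain boundary also lowers contact across a bin, and the anchors were not compared with boundaries in general. These values therefore cannot tell a junction from a boundary. The median percentile was 66.6 at the stripes, with a lower quartile of 25.8. It was 25.3 over stripes and two-sided contacts together, as the test was first laid out. A junction thus stays open for every shape. An extra copy of a short sequence stays open for the stripes. Their bins had a median of 1.05 times the contacts per fragment of their neighbours, spread from 0.886 to 1.60. No biological explanation was tested, as the design has 1 group.

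The compartment classes without the arm-scale trend followed the density of restriction fragments, with a rank correlation across bins from 0.466 on 2R to 0.631 on 3R. Among bins of the middle tercile of fragment density the strength was still 1.48, so the separation did not need the extremes of fragment density. The classes came from these same contacts within arms, and no shifts were run for the tercile. That value therefore does not settle how far fragment density is a cause. The same classes had a strength of 1.19 in contacts between arms of different chromosomes, which had not been used to draw them (highest of 1000 shifts 1.02), so a fit to noise is not enough. Whether they only part bins at boundaries from the interiors of domains was not tested, nor were gene density and chromatin state.

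The higher ratio of contact within to across domains on X might come from the lower depth of X. Autosomal arms thinned to the depth of X kept a mean ratio of 1.64 (SD 0.0249, n = 4 arms) against 1.89 on X, which argues against depth. The steeper decay of X at short range stays open: beyond 100 kb the ratio of X was 1.04 times that of the highest autosomal arm, a margin smaller than the SD over autosomal arms. Copy number and pairing of homologous chromosomes were not tested.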

How the results depend on the processing

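The centred and trend-free eigenvectors, the random split of the contacts, the median contact between arms, the permutation of arm labels, compartment strength between arms and the thinned autosomes were added after seeing the data. Of the alternatives to the main results, 108 kept the direction and the side of the threshold or stayed within the spread, 12 moved, 7 lost the call and 5 changed direction; the cause was not tested for any of these. The ratio within against across domains was above all 1000 shifts in every alternative run, including each arm left out; from 20 to 100 kb its boundaries came from the same contacts, and p was at its floor throughout. Boundaries numbered 984 with a 50 kb window and 354 with a 200 kb window. The share of contacts within arms was 89.0% on major arms only. The decay slope from 10 to 100 kb was -0.643 with the authors' expected values. For X against autosomes, the slope difference was -0.0595 with raw contacts, the ratio of ratios was 1.11 with a 200 kb window and 1.12 with raw contacts, and the difference in domain size was 0.475 kb with a 50 kb window, -20.7 kb with a 200 kb window, -12.5 kb at a prominence of 0.1, -40.7 kb at 0.4 and -7.45 kb with raw contacts. Compartment strength was 1.11 at 160 kb. Sign changes near a boundary, not above chance in the fixed version, were 27.5% at 20 kb (no shift was lower), 40.7% at 80 kb, 33.7% at a prominence of 0.4, 55.4% after centring and 54.5% without the trend; only the last 2 passed the test. The ratio of same-chromosome to other arm pairs, 1.48, counts as a lost call under the exact permutation of arm labels. That loss was fixed by the design: the permutation has 15 arrangements and gave its smallest possible p, 0.0667. The Rabl-like rho was -0.111 at 80 kb, -0.00926 with raw contacts and -0.0810 without 2 Mb at each end. Distal contacts numbered 1242 at 20 kb, 42 at 80 kb, 570 at a threshold of 3, 38 at a threshold of 6 and 628 with raw contacts. Of all boundaries, 51.7% (200 kb window) to 100% (prominence of 0.1) had a boundary within 20 kb under an alternative. The 100% was fixed in advance, as a lower prominence keeps every boundary, and no share for shifted positions was computed. Of the named boundaries, 43 of 45 alternatives kept a boundary within 20 kb. Those at other prominences were fixed in advance, as the named boundaries are the most prominent of their arms. Of the longest domains 29 of 42 stayed within 1.5 times their size. Another 3 gave no size, 2 because too few bins passed the coverage filter and 1 because a boundary fell on the midpoint. No paired analysis was possible because the maps do not separate the 2 samples. Gene lists were not run, as no annotation of the assembly was used, and the comparison at 110 to 200 kb was not run with a 200 kb window, which would have used those contacts. Depth limits pairs of distant bins most: the median pair of 80 kb bins of different arms held 11 contacts.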

Other observations

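The ends of arms were compared after the map had been viewed. Telomeric ends of arms of different chromosomes met 2.13 times as often as their arms did on average (SD 2.27, 8 arm pairs), with 5 of 8 above 1 and a range from 0.693 to 7.57. Centromeric ends met 1.64 times as often (SD 0.830), with 7 of 8 above 1. A centromeric with a telomeric end gave 0.684 (SD 0.171, 16 combinations). Each end was the outermost 0.96 Mb that passed the filter.

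The classes without the arm-scale trend had their higher contact within arms in the boundary-rich class, at 1.57 ± 0.132 of the value for distance against 0.929 ± 0.0458 in the boundary-poor class (SD, n = 5 arms). Between chromosomes the order was the opposite, 1.07 against 1.13. The difference between the classes was not tested.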
